A study of Mus musculus with 16 samples.

How the data were processed

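RNA from mouse intestinal organoids, crypt cells grown as closed epithelial structures in a gel matrix, was sequenced in 16 libraries. Per the labels' protocols, the cells carried a tamoxifen-inducible Cre recombinase with or without an Apc gene flanked by recombination sites, and Apc was recombined in culture. The same protocols state that wild type organoids carried a red and mutant organoids a green fluorescent construct. Conditioned medium, culture medium taken from other organoid cultures and refreshed with R-spondin, Noggin and EGF, came from wild type or Apc mutant cultures per the labels' protocols, and the treatment label names Apc mutant medium for all 12 treated libraries. Libraries were made from total RNA with ribosomal RNA depletion, per the labels' protocols, but the RNA content of the untreated libraries, given below, goes against that.

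The authors deposited 1 table of raw read counts per library, with whole-number counts for 46078 Ensembl genes and 5 summary lines in the format of htseq-count. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0 and HTSeq 0.6.1p1 were used with the mouse build GRCm38. The notes give no options for these tools. The strand setting and the release of the gene annotation are not given in the sources used here, so overlapping genes on opposite strands could not be separated. Reads with more than 1 alignment stand in a summary line and in no gene, so genes with near-identical copies, such as histone, Defa, Cyp2c, Gbp, Ifit and Ifitm family members, are uncertain. Gene symbols and GRCm38 coordinates came from the GENCODE M21 annotation, which gave a symbol for 45143 of the identifiers (98.0%).

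The summary lines were left out of library sizes and tests. Reads outside annotated features made up 14.4 to 19.2% of all reads in the 12 conditioned medium libraries and 4.78 to 7.32% in the 4 untreated ones. Reads with several alignments made up 26.5 to 33.3% and 36.5 to 38.9%, reads that did not align 7.35 to 9.41% and 2.77 to 3.02%, in the same order. Ambiguous reads made up 0.460 to 0.599% in all 16. Counts assigned to genes came to 17986815 to 29152692 per library in conditioned medium and 8325979 to 13027701 without it. A group of 3 libraries at 0 counts therefore bounds a gene below a lower CPM than a group of 2, and differences in weakly expressed genes are less certain in the untreated groups.

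Samples were grouped by the genotype, treatment and culture day in the labels into 6 groups. There were 3 libraries each of Apc mutant and wild type organoids in conditioned medium on day 2 and on day 4, and 2 each of untreated Apc mutant and wild type organoids on day 2. The design stated for the series instead lists 3 libraries of each genotype without conditioned medium on each day and 3 of each with it on day 2, and the labels of the libraries were followed. Libraries within a group were compared with each other first. No pair held the same library, as the chi-square over genes per degree of freedom lay between 3.49 and 46.4. Both values above 7 (43.9 and 46.4) were from pairs with replicate 1 of wild type on day 4 in conditioned medium, which also had 33.3% of reads with several alignments.

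Differential expression was tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in a single fit of all 6 groups, with TMM scaling (factors 0.898 to 1.26) and the filterByExpr filter on low counts, which kept 16510 genes. Sharing the spread over the groups left 10 residual degrees of freedom and a common biological coefficient of variation of 5.96%. An adjusted p under 0.05 was the threshold. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The 9 comparisons were genotype without conditioned medium on day 2, genotype within conditioned medium on day 2 and on day 4, conditioned medium within each genotype on day 2, day within each genotype in conditioned medium, and the interactions of genotype with conditioned medium and with day.

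The comparisons, the tests, most alternatives, the naming rule and 25 gene lists with 380 members were fixed before the data were examined. The lists were Wnt/beta-catenin target genes, secreted Wnt antagonists, crypt base stem cell genes, absorptive enterocyte genes, goblet cell genes, Paneth cell genes, enteroendocrine cell genes, tuft cell genes, cell cycle genes, fetal-like and regenerative epithelium genes, YAP target genes, BMP target genes, Notch pathway and secretory fate genes, interferon-stimulated genes, NF-kB and chemokine genes, hypoxia and glycolysis genes, ATF4 and amino acid response genes, cholesterol synthesis genes, fatty acid oxidation and ketogenesis genes, p53 target genes, oxidative stress (NRF2) genes, ribosome biogenesis and nucleolar genes, and markers of fibroblast and stromal, immune, and endothelial and neural cells. List members were taken from general knowledge of the tissue, not chosen on these samples. Each list was tested with fry, which asks whether its genes moved, on balance, 1 way, and again with camera, which compares the list with all other genes, once with an estimated and once with a preset inter-gene correlation of 0.01.

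Named genes were, per comparison, Apc, Axin2, Lgr5, Notum, Wif1 and Dkk2, the 5 genes with the largest and the 5 with the smallest log2 fold change among those called, and up to 4 members of each list with the smallest p. The largest changes were taken among genes with a mean of at least 5 CPM in the higher group, no overlap between the libraries of both groups and an assigned gene name, with overlap not considered for interactions. Levels in CPM were computed from the deposited counts with TMM-scaled library sizes. Where every library of a group was at 0, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, the exact 95% interval of the ratio of counts is given. These floors and intervals cover counting error only, since reads were not counted as molecules. Fitted fold changes of such genes depend on the prior count, so list medians are given also with such genes at their bound. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

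The procedure was tested on simulated data with the real library sizes and means and 200 changed genes, over 15571 to 15612 genes per comparison. Across the 9 comparisons it recovered 64.2 to 85.1% of genes changed 1.5-fold, 80.9 to 97.1% of those changed 2-fold and 93.8 to 100% of those changed 4-fold. Wrong calls made up 3.50 to 6.67% of all calls. A changed gene list was recovered in 9 of 9 comparisons and 0 of 170 tests of unchanged lists passed with fry. In the real data up to 74.4% of genes were called in a comparison, far more than the 200 changed here. These rates therefore do not cover comparisons in which most genes changed.

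Alternatives were DESeq2's size factors, no filter, a stricter filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0 as the test, a fit of only the groups compared, mitochondrial genes left out, a fold threshold, each library left out in turn, the replicate number as a block, and camera in place of fry. Other alternatives were chosen after the data had been seen, namely fits without the untreated libraries, without the genes Gm26917 and Gm42418, with protein-coding genes other than replication-dependent histone genes, and with crossed replicate numbers. The labels number libraries 1 to 3 in each conditioned medium group. For day within the labelled mutant libraries, deviations from the group means over 9818 genes correlated at 0.114 to 0.186 between libraries of the same number. This was above 0.1 for every pair, and these numbers were read as pairs from this hint in the data, since no label says what a number shares. The hint was weak, as only 2 of 3 day 4 libraries were closest to their own number. For day in wild type, libraries of different numbers correlated at up to 0.233.

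Reads were not analysed here, so the recombined part of Apc was not measured separately from the rest of the gene. Plots were drawn with matplotlib 3.10.9. The result of 1 gene is not reported here.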

Results

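RNA was sequenced from 16 libraries of mouse intestinal organoids, which hold the stem, progenitor and differentiated cells of the gut epithelium. The study compared Apc mutant with wild type organoids and followed both in conditioned medium, in order to ask how mutant cells act on the cells around them. Apc encodes a scaffold of the complex that degrades beta-catenin, and its loss turns on Wnt target genes. Libraries fell into 6 groups by their labels, with n = 3 for Apc mutant and for wild type organoids in conditioned medium on day 2 and again on day 4, and n = 2 for untreated Apc mutant and untreated wild type organoids on day 2. The design given for the whole series differs, as it names untreated organoids on both days and conditioned medium on day 2 alone, so day 4 and untreated values rest on the labels of single libraries. Counts assigned to genes ranged from 8325979 to 29152692 per library, with a median of 20401083. The 12 conditioned medium libraries held at least 17986815 counts and the 4 untreated libraries at most 13027701. Levels are given as mean CPM ± SD over the libraries of a group, fold changes on the log2 scale carry a standard error (SE), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16510 genes. For genes named as higher or lower in a comparison of 2 groups, no library of one group reached into the range of the other.

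The targeted gene was examined first, as a check of the labels. Apc (ENSMUSG00000005871, GRCm38 chromosome 18, 34220924 to 34322552) was read in every library. It stood at 252 to 278 CPM in the labelled mutant and 246 to 260 CPM in the labelled wild type libraries in conditioned medium on day 2, and at 266 to 281 and 237 to 269 CPM on day 4. Without conditioned medium it stood at 217 and 249 CPM in mutant and at 69.3 and 76.1 CPM in wild type libraries (log2 fold change 1.68, SE 0.08, adjusted p = 2.2e-15). Counts over the whole gene do not separate the recombined part, so they neither show nor exclude the deletion. Targets of the pathway were more telling. Notum, a secreted enzyme that inactivates Wnt proteins, reached 285 ± 38.6 CPM (SD, n = 2) in untreated mutant libraries, against 0.273 ± 0.0769 CPM in untreated wild type. In conditioned medium Notum stayed at or below 1.03 CPM in all 12 libraries of either label. Nkd1, a feedback inhibitor of Wnt signalling, stood at 486 ± 65.6 CPM in untreated mutant libraries and at 1.61 ± 0.101 and 1.76 ± 0.521 CPM in the labelled mutant libraries in conditioned medium on days 2 and 4. Dkk2, a secreted Wnt antagonist, stood at 3.09 ± 0.732 CPM (SD, n = 2) in untreated mutant libraries and at 0 counts in all others. These targets went against the genotype label of the 6 mutant libraries in conditioned medium, which are called the libraries labelled Apc mutant from here on. Every direction between genotypes within conditioned medium rests on those labels. The titles of the 12 conditioned medium libraries hold APCCM or WTCM, which can name the genotype of the cells or the source of the medium. Differences between these labels may therefore be differences of medium source rather than of genotype.

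**Figure D1:**
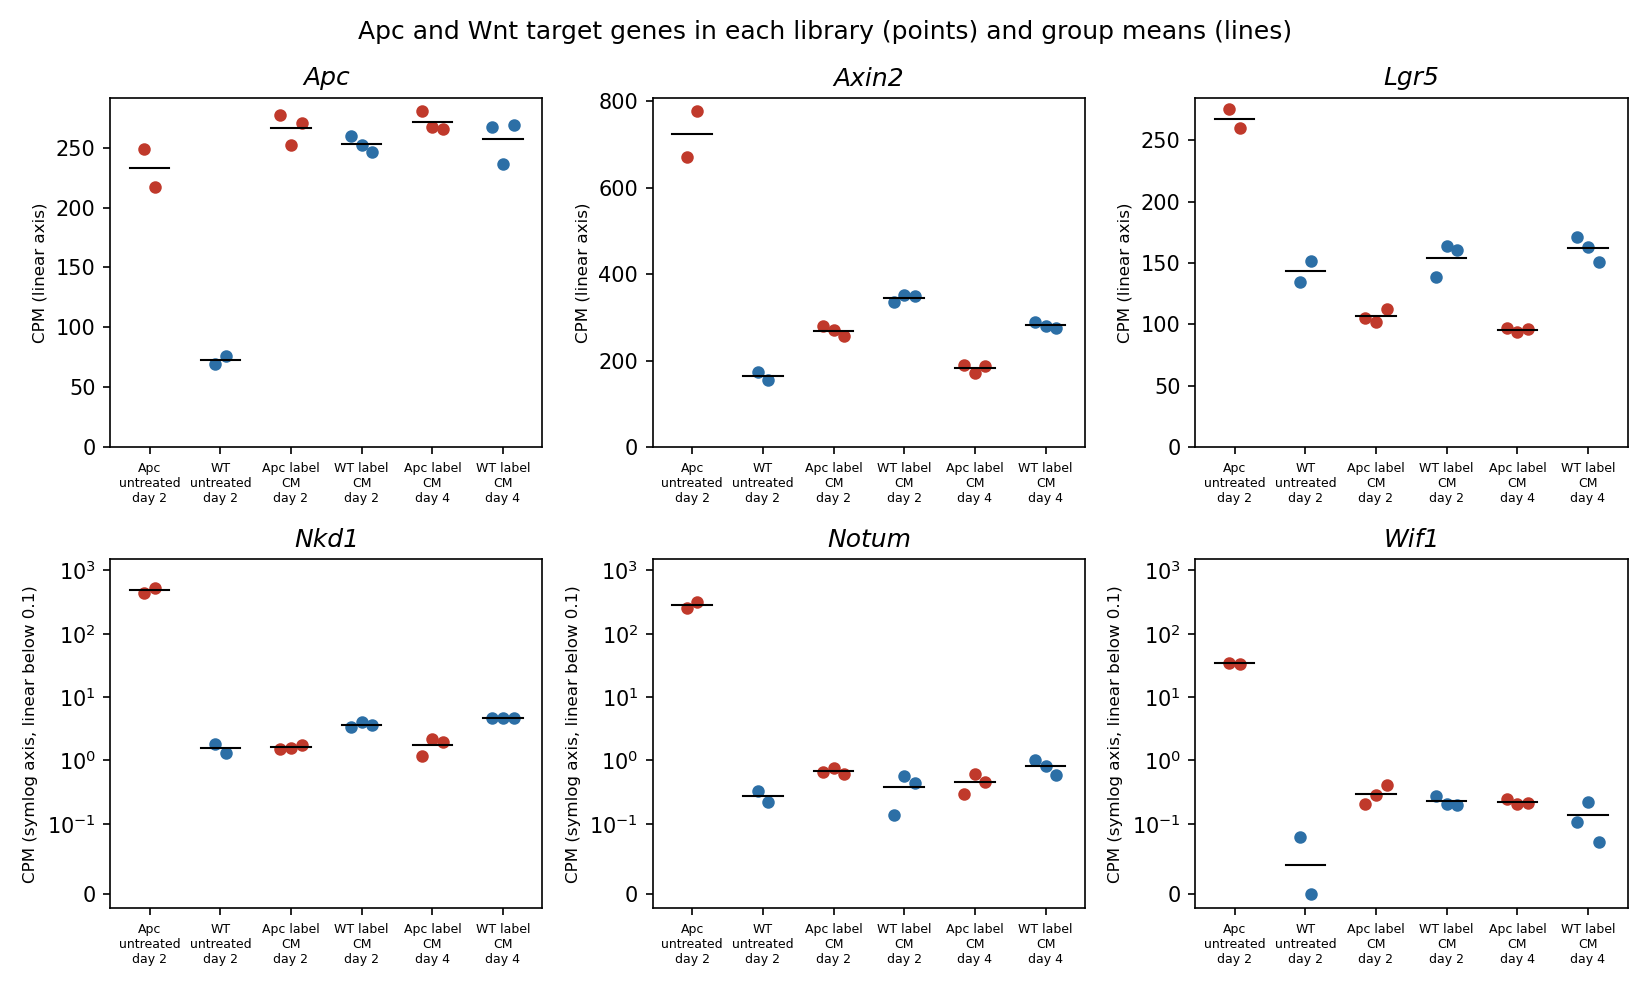
Levels in CPM of Apc, Axin2, Lgr5, Nkd1, Notum and Wif1 in each of the 16 libraries (points) with group means (lines), with a linear axis for the first 3 genes and a log axis that is linear below 0.1 CPM for the others. Notum and Nkd1 reached 285 and 486 CPM on average in untreated mutant libraries and stayed under 5 CPM on average in all 5 other groups.

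Both media classes also differed in RNA content. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, summed to 4689 to 5520 CPM in the group means of conditioned medium libraries over 60 genes, against 41.7 and 45.5 CPM in the untreated groups. The 182 genes of small nuclear, nucleolar and related RNAs summed to 5137 to 7705 CPM against 104 and 94.2 CPM. Gm26917 alone took 7.68 to 11.5% of gene counts in conditioned medium and 0.00387 to 0.00952% without it. The near absence of RNAs without a poly(A) tail in untreated libraries goes against the total RNA preparation stated in the labels' protocols. How those libraries were made was not resolved here. Xist, the X-inactivation RNA, stood at 1939 to 3707 CPM in untreated libraries and at 1.17 to 11.4 CPM in conditioned medium, where the Y-linked gene Ddx3y stood at 86.9 to 129 CPM. Comparisons of conditioned medium with untreated libraries therefore also compare libraries of different RNA content from cells of different sex chromosome expression.

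Genotype was compared first without conditioned medium, on day 2, to describe the mutant program (n = 2 and n = 2). Untreated Apc mutant organoids carried far more Wnt target transcripts and far fewer transcripts of differentiated cells than wild type. Nkd1 rose 305-fold (log2 8.25, SE 0.15) and Prox1, a homeobox transcription factor, rose 253-fold, from 3.73 ± 0.961 to 968 ± 61.9 CPM. Axin2, a negative regulator and standard readout of the pathway (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), rose 4.38-fold (adjusted p = 7.3e-18). Sucrase-isomaltase (Sis), a brush border enzyme of enterocytes, fell from 3063 ± 232 to 9.95 ± 1.71 CPM. Lysozyme (Lyz1), an antimicrobial enzyme of Paneth cells, fell from 2536 ± 103 to 5.84 ± 0.220 CPM. In total 10319 of 16510 genes passed the threshold, 5348 higher and 4971 lower in the mutant, and 4779 of them changed at least 2-fold.

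Of 18 tested Wnt/beta-catenin target genes, 17 were higher and 0 lower, over all genes and also adjusted over the list alone, with a median log2 fold change of 2.01 (fry adjusted p = 3.9e-13). Tnfrsf19, a receptor of the TNF family, reached 659 ± 18.4 against 12.4 ± 0.992 CPM. Of 6 secreted Wnt antagonists, 4 were higher, or 5 adjusted over the list alone, with a median of 5.63, or 3.42 with the gene at 0 placed at its bound (fry adjusted p = 6.5e-11). Notum (ENSMUSG00000042988, chromosome 11, 120653788 to 120661175) rose 994-fold (log2 9.96, SE 0.21). Wif1 (chromosome 10, 121033960 to 121100650) reached 34.0 ± 0.382 CPM against 1 count in wild type, a ratio with a counting interval of 130 to 28784. Dkk2 (chromosome 3, 132085292 to 132180304) was at least 21.8-fold higher. Crypt base stem cell genes split, with 8 higher and 6 lower of 14. Lgr5, the R-spondin receptor that marks crypt stem cells (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780), rose by a log2 of 0.91 (SE 0.08, adjusted p = 3.0e-10), while Olfm4, a secreted glycoprotein of the same cells, fell from 1982 ± 126 to 0.257 ± 0.0693 CPM. The median of this list was 0.48, its mean -0.90 and its test pointed down (fry adjusted p = 0.00023), a call lost at adjusted p = 0.75 with an estimated correlation.

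Genes of enterocytes and of goblet, Paneth and enteroendocrine cells were lower. Among absorptive enterocyte genes 21 of 22 fell, with a median of -7.99, or -7.53 with genes at 0 at their bound (fry adjusted p = 2.3e-13). Alkaline phosphatase Alpi fell from 1396 ± 20 to 0.131 ± 0.0115 CPM. All 11 goblet cell genes fell (median -4.33, fry adjusted p = 8.5e-12), among them the mucus protein genes Fcgbp and Zg16. Of 12 Paneth cell genes, 10 fell and 2 rose (median -6.72), although members of the Defa family share near-identical sequence and are uncertain. Of 16 enteroendocrine cell genes 13 fell, or 14 adjusted over the list alone, and 1 rose (median -6.21, or -5.94 at the bound). Chgb, a granule protein of hormone cells, fell from 283 ± 6.08 to 3.79 ± 0.263 CPM and the incretin gene Gip was at least 750-fold lower. Of 10 tuft cell genes 8 fell and 1 rose (median -2.04, fry adjusted p = 0.00028, adjusted p = 0.74 with an estimated correlation). The 1 that rose was Ptgs1, a prostaglandin synthase, at 51.6 against 2.22 CPM.

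Fetal-like and regenerative epithelium genes went up, with 10 of 12 higher and 0 lower (median 2.64, fry adjusted p = 4.1e-08), a call lost at adjusted p = 0.086 with an estimated correlation. The alarmin Il33 rose 66.6-fold and the surface protein gene Ly6a 14.3-fold. Of 11 YAP target genes 8 rose and 3 fell (median 3.04, adjusted p = 0.086 with an estimated correlation), and the matrix protein gene Ccn2 rose from 0.641 ± 0.134 to 54.8 ± 2.54 CPM. Of 10 BMP target genes 7 rose and 1 fell (median 1.70, adjusted p = 0.086 with an estimated correlation), with Id3, an inhibitor of differentiation factors, at a log2 of 3.29 (SE 0.22). ATF4 and amino acid response genes rose in 15 of 17, with 1 lower (median 1.19, fry adjusted p = 4.3e-10), and the serine synthesis gene Psat1 by a log2 of 1.76 (SE 0.09). p53 target genes rose in 12 of 15 with 2 lower (median 1.02), cholesterol synthesis genes fell in 18 of 19 (median -1.14), and fatty acid oxidation and ketogenesis genes fell in 12 of 15 with 3 higher (median -1.01). Each of these 3 lists was lost at adjusted p = 0.086 with an estimated correlation. Interferon-stimulated genes were mixed, with 7 higher and 4 lower of 18 (median 0.36, fry adjusted p = 0.060), and hypoxia and glycolysis genes fell in 11 of 19 with 5 higher (median -0.19, fry adjusted p = 6.4e-06, adjusted p = 0.55 with an estimated correlation). The carbonic anhydrase gene Car9 fell by a log2 of -3.14 (SE 0.11), while Vegfa, an angiogenic growth factor, rose by 0.78. Ribosome biogenesis and nucleolar genes fell in 13 of 17 (median -0.42), with Dkc1 at -1.13 (fry adjusted p = 7.5e-09, adjusted p = 0.24 with an estimated correlation). Fibroblast and stromal cell markers, with 3 of 11 members tested and levels under 1 CPM, passed at fry adjusted p = 0.045, lost at adjusted p = 0.87 with an estimated correlation. Endothelial and neural cell markers had a median of 0.78 and a mean of -0.81 and did not pass (fry adjusted p = 0.82). Immune cell markers, with 3 of 12 members tested, had 1 higher and 1 lower and did not pass (fry adjusted p = 0.89). Cd68 stood at 6.67 against 1.31 CPM and Itgam at 0.161 against 2.00 CPM. Reads outside annotated features made up 7.09 ± 0.329% of all reads in untreated mutant and 4.90 ± 0.166% in untreated wild type libraries. With 2 libraries per group these values rest on a spread shared with the other groups. Untreated mutant and wild type organoids also differed in HoxA cluster genes, in genes with regional expression and on chromosome 19, as given below. Effects of Apc cannot be told apart here from other differences between these organoids.

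**Figure D2:**
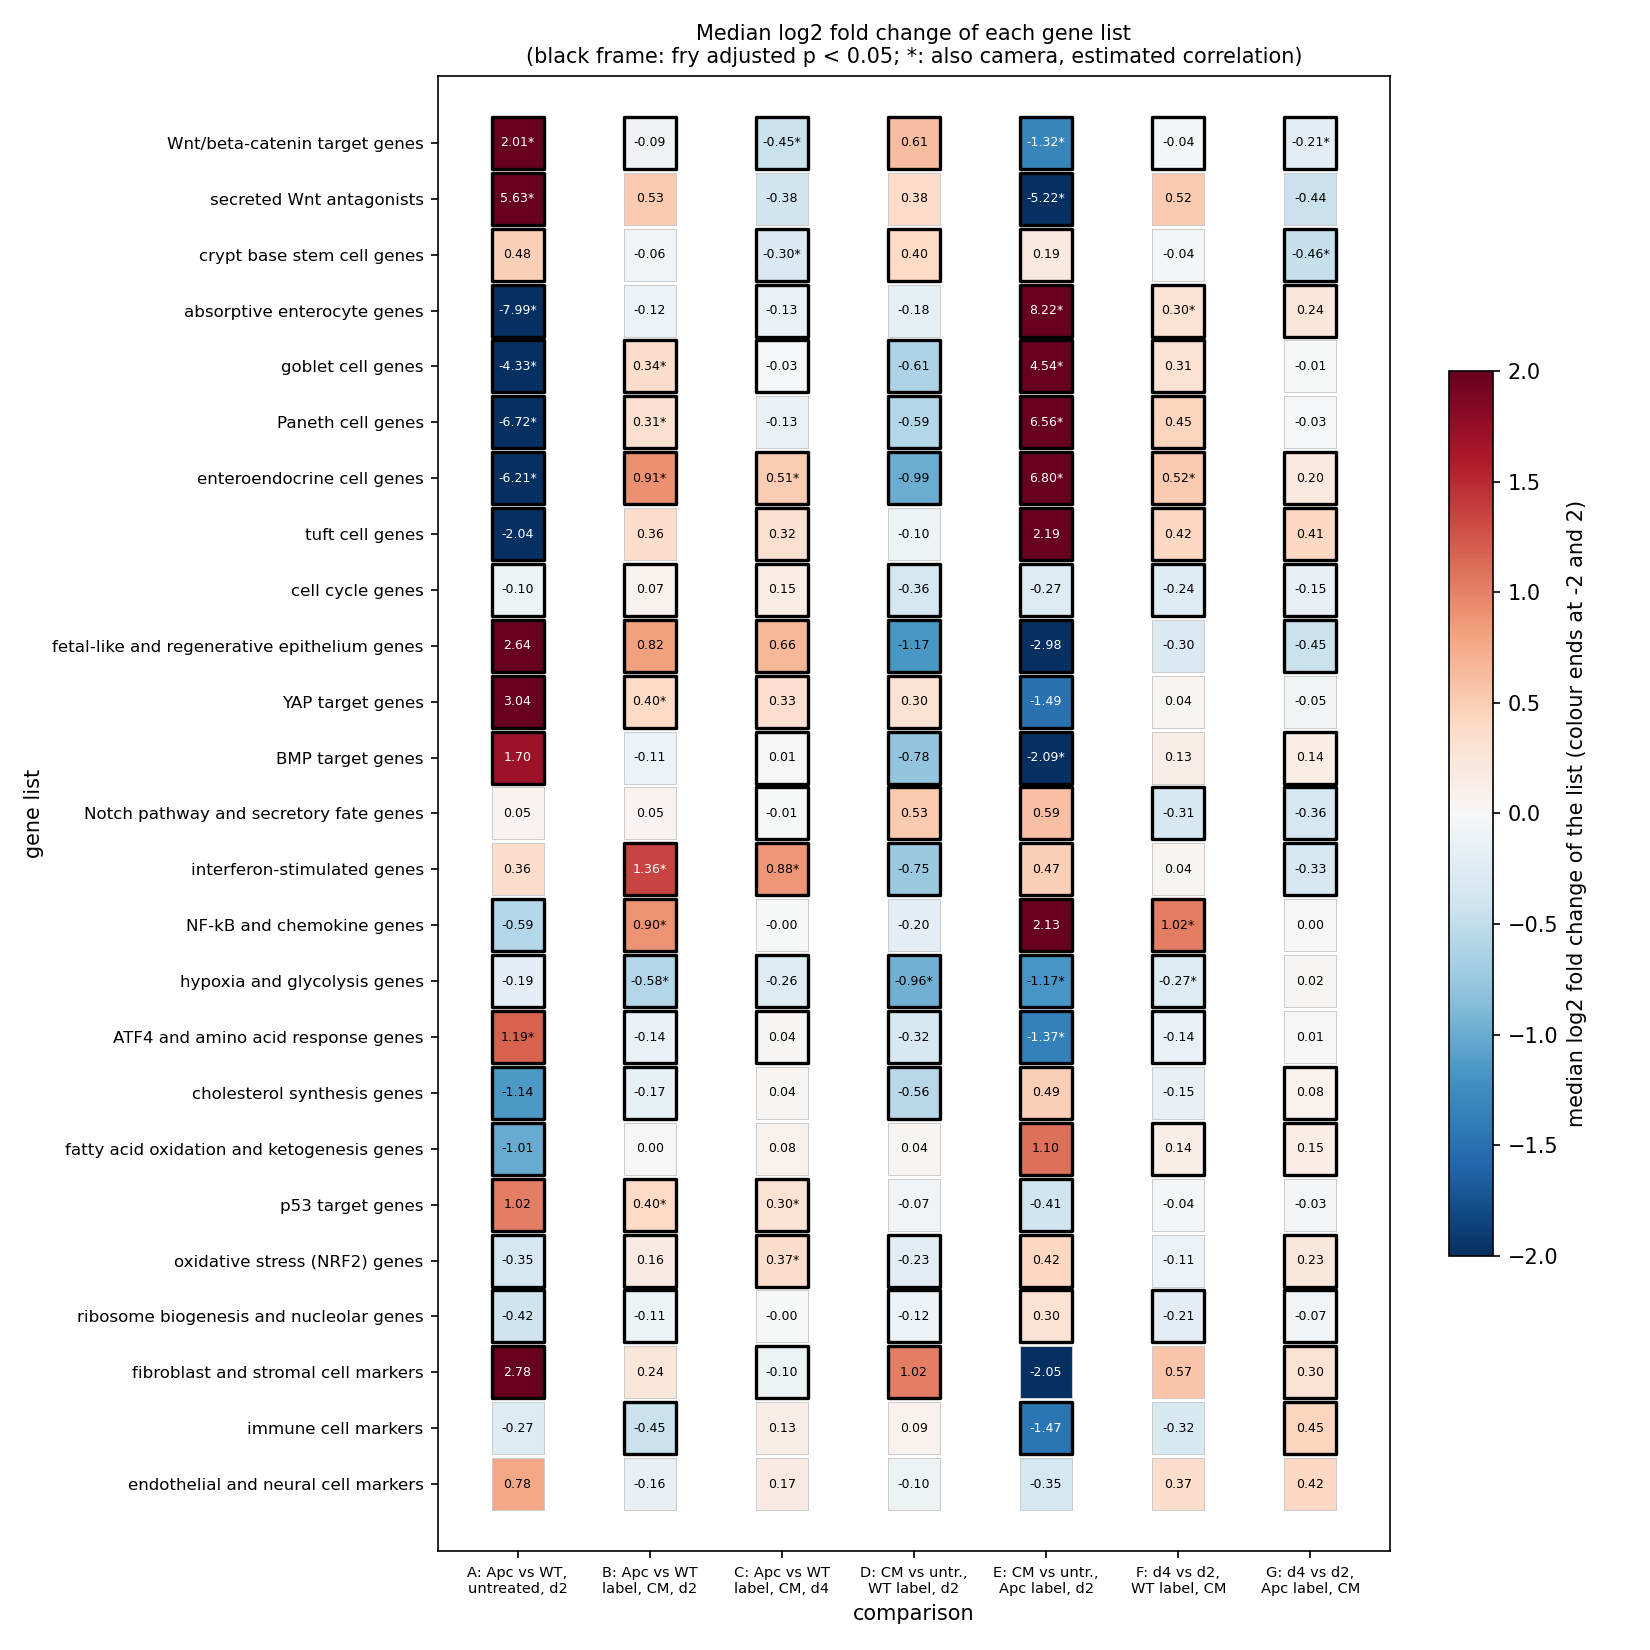
Median log2 fold change (number and colour, colour ending at ±2) of the tested members of 25 gene lists (lines) in 7 comparisons (columns), with black frames at fry adjusted p under 0.05 and stars where camera with an estimated correlation also passed. Enterocyte genes had a median of -7.99 in untreated mutant over wild type and 8.22 in conditioned medium over untreated among mutant-labelled libraries.

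Genotype was then compared within conditioned medium on day 2 (n = 3 and n = 3). In the libraries labelled Apc mutant, interferon-stimulated genes were higher and hypoxia and glycolysis genes lower than in the libraries labelled wild type, while Wnt targets were not raised. Oasl2, an interferon-induced protein related to antiviral synthetases (ENSMUSG00000029561, chromosome 5, 114896936 to 114912234), stood at 19.2 ± 3.58 against 1.05 ± 0.384 CPM (SD, n = 3), an 18.2-fold difference (log2 4.18, SE 0.24, adjusted p = 8.5e-12). Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), stood at 70.6 ± 3.60 against 8.75 ± 1.35 CPM (log2 3.02, SE 0.12). Ndrg1, a gene induced by low oxygen, was lower at 174 against 342 CPM (log2 -0.97, SE 0.05, adjusted p = 2.8e-12). Apc differed by a log2 of 0.08 (SE 0.06, adjusted p = 0.41). In total 2755 genes passed, 1410 higher and 1345 lower in the libraries labelled mutant, of which 311 changed at least 2-fold. The count was 1725 without replicate 3 of the labelled mutant group, of which 1668 were among the 2755.

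Of 18 interferon-stimulated genes 16 were higher and 0 lower, or 17 adjusted over the list alone (median 1.36, fry adjusted p = 2.4e-08, adjusted p = 0.00013 with an estimated correlation). The transcription factor Irf7 stood at 25.4 against 6.48 CPM, and Stat2, which carries the interferon signal to the nucleus, was higher by a log2 of 0.93 (SE 0.07). Of 19 hypoxia and glycolysis genes 17 were lower and 0 higher (median -0.58, adjusted p = 0.00015 with an estimated correlation), with the glycolytic enzymes Pgk1 and Aldoa at -0.83 and -0.76. Of 10 NF-kB and chemokine genes 7 were higher (median 0.90, fry adjusted p = 2.5e-06), with the cytokine gene Tnf at 8.21 against 1.80 CPM and the chemokine gene Ccl20 at 22.5 against 7.41 CPM. p53 target genes were higher in 11 of 15, or 13 adjusted over the list alone, with 0 lower (median 0.40). Both lists held with an estimated correlation at adjusted p = 0.0046.

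Goblet, Paneth and enteroendocrine cell genes were higher as lists in the libraries labelled mutant, while tuft cell genes did not pass (fry adjusted p = 0.052). These are RNA levels, and numbers of cells were not measured. Of 11 goblet cell genes 9 were higher and 0 lower (median 0.34, adjusted p = 0.0046 with an estimated correlation). Muc2, the gel-forming mucin, stood at 727 ± 112 against 343 ± 17.3 CPM and Clca1, a secreted mucus protein, at 243 ± 13.7 against 79.4 ± 10.6 CPM. Of 12 Paneth cell genes 6 were higher (median 0.31, adjusted p = 0.038 with an estimated correlation), with the protease gene Mmp7 at a log2 of 1.07 (SE 0.07). Of 16 enteroendocrine cell genes 11 were higher, or 14 adjusted over the list alone, and 1 lower (median 0.91, adjusted p = 0.0027 with an estimated correlation). Of 12 fetal-like and regenerative epithelium genes 9 were higher (median 0.82, fry adjusted p = 0.0017, adjusted p = 0.081 with an estimated correlation), with Ly6a at 14.9 against 5.16 CPM. Of 11 YAP target genes 3 were higher and 1 lower, or 6 and 1 adjusted over the list alone (median 0.40, adjusted p = 0.047 with an estimated correlation). Areg, a ligand of the EGF receptor, stood at 85.4 against 33.7 CPM.

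Wnt/beta-catenin target genes were lower in 7 and higher in 2 of 18, or 8 and 2 adjusted over the list alone (median -0.09, fry adjusted p = 0.0040, adjusted p = 0.25 with an estimated correlation). Axin2 was lower by a log2 of -0.36 (SE 0.06, adjusted p = 0.00012), Lgr5 by -0.54 (SE 0.06) and Nkd1 by -1.18 (SE 0.19), and Ccnd1, a cyclin of the G1 phase, was higher by 0.33. Notum stood at 0.676 against 0.383 CPM (adjusted p = 0.18). Immune cell markers, with 3 of 12 members tested, were lower (median -0.45, fry adjusted p = 0.0040, adjusted p = 0.28 with an estimated correlation). Lists that did not pass included absorptive enterocyte genes, in which 5 were higher and 7 lower of 22, among them the peptidase gene Anpep at 0.83 and the apolipoprotein gene Apoc3 at -0.69. Reads outside annotated features made up 17.7 ± 1.84% of all reads in the labelled mutant and 15.5 ± 1.09% in the labelled wild type libraries.

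The same contrast on day 4 asked whether the difference held over time (n = 3 and n = 3). Interferon-stimulated genes were again higher and stem cell genes were lower in the libraries labelled mutant. Oasl2 stood at 10.5 ± 3.23 against 0.549 ± 0.259 CPM (log2 4.31, SE 0.28, adjusted p = 1.1e-10). Olfm4 (ENSMUSG00000022026, chromosome 14, 79984081 to 80023139) stood at 1379 ± 92.3 against 2861 ± 48.0 CPM (log2 -1.05, SE 0.05, adjusted p = 1.2e-12) and Lgr5 at 95.8 ± 1.86 against 162 ± 10.3 CPM. Isx, a homeobox repressor of carotenoid and vitamin A uptake, stood at 104 ± 2.58 against 21 ± 6.55 CPM, while Bco1, the enzyme that cleaves beta-carotene and a target of that repressor, stood at 4.74 against 27.0 CPM (log2 -2.50, SE 0.14). In total 2580 genes passed, 1293 higher and 1287 lower, of which 286 changed at least 2-fold.

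Of 14 crypt base stem cell genes 9 were lower and 0 higher, or 10 adjusted over the list alone (median -0.30), and of 18 Wnt/beta-catenin target genes 10 were lower and 1 higher, or 13 and 1 adjusted over the list alone (median -0.45). Both passed at fry adjusted p = 3.0e-06 and at adjusted p = 0.0062 with an estimated correlation. Rgmb, a BMP co-receptor of stem cells, was lower by a log2 of -0.73 (SE 0.05), Axin2 by -0.62 (SE 0.06) and Tnfrsf19 by -1.59 (SE 0.13). Interferon-stimulated genes were higher in 14 of 18, or 16 adjusted over the list alone, with 0 lower (median 0.88, adjusted p = 0.0017 with an estimated correlation). Oxidative stress (NRF2) genes were higher in 12 of 15 with 0 lower (median 0.37, adjusted p = 0.017 with an estimated correlation), with the glutathione transferase gene Gstm1 at 739 against 380 CPM and the quinone reductase gene Nqo1 at a log2 of 0.90 (SE 0.09). p53 target genes were higher in 10 of 15, or 11 adjusted over the list alone (median 0.30), and enteroendocrine cell genes in 8 of 16, or 9, with 1 lower (median 0.51), at adjusted p = 0.014 and 0.017 with an estimated correlation. The cell cycle inhibitor gene Cdkn1a was higher by 0.66 (SE 0.06) and the glucagon gene Gcg by 2.02 (SE 0.27).

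Other lists passed fry but were lost with an estimated correlation. Hypoxia and glycolysis genes were lower in 9 and higher in 2 of 19 (median -0.26, adjusted p = 0.055 with an estimated correlation), and fetal-like and regenerative epithelium genes were higher in 8 of 12 (median 0.66, adjusted p = 0.17 with an estimated correlation). Cell cycle genes were higher in 9 of 22, or 12 adjusted over the list alone (median 0.15, adjusted p = 0.27 with an estimated correlation), with the proliferation marker Mki67 at 800 against 659 CPM. Goblet cell genes had a median of -0.03 but a mean of 0.26 and a test that pointed up (fry adjusted p = 0.0050, adjusted p = 0.30 with an estimated correlation), with Clca1 at 1.44 and Muc2 at 0.33. Fibroblast and stromal cell markers likewise had a median of -0.10, a mean of 0.16 and a test that pointed up (fry adjusted p = 0.044, adjusted p = 0.54 with an estimated correlation). BMP target genes, 1 higher of 10, or 2 adjusted over the list alone, had a median of 0.01 and a mean of -0.04 and passed upward at fry adjusted p = 0.044, which was lost at adjusted p = 0.63 with an estimated correlation. Paneth cell genes were 3 higher and 4 lower of 12 and did not pass. The number of lists past the threshold was 17, and 11 without replicate 3 of the labelled mutant group, replicate 1 of the labelled wild type group or replicate 3 of the labelled wild type group. Replicate 1 of the labelled wild type group stood apart, with Gm42418 at 5.74% of its gene counts and at 1.90 to 2.37% in the 5 other day 4 libraries. Reads outside annotated features made up 17.6 ± 1.2 and 14.9 ± 0.341% of all reads, in the same order.

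Calls of both days were shared more often than independent lists would give. There were 670 genes higher on both days, with 110 expected from independent calls, and 604 lower on both, with 105 expected, while 12 and 13 went in opposite directions. Log2 fold changes correlated across genes at a Pearson r of 0.36 and a Spearman rho of 0.44, and genes are not independent replicates. Against the untreated genotype comparison, calls on day 2 shared 595 higher genes, with 457 expected, and 764 lower genes, with 405 expected, while 287 went from higher to lower, with 436 expected, and 481 from lower to higher, with 425 expected (Pearson r of 0.10). On day 4 the untreated comparison shared 437 higher genes, with 419 expected, and 527 lower genes, with 388 expected, while 511 went from higher to lower, with 417 expected, and 531 from lower to higher, with 389 expected (Pearson r of 0.014).

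Conditioned medium was compared with no treatment in wild type organoids on day 2, to ask how the medium changed normal cells (n = 3 and n = 2). Replication-dependent histone genes led the genes that were higher in conditioned medium and Xist led those that were lower. Hist1h4d stood at 325 ± 40.4 CPM in conditioned medium and at 0 without it, at least 2327-fold higher, as one of a multigene family with uncertain assignment. Xist (chromosome X, 103460366 to 103483254) fell 991-fold, from 2071 ± 185 to 2.08 ± 0.860 CPM, and Eif2s3y, a Y-linked translation factor gene, was at least 844-fold higher. Apc rose from 72.7 ± 4.83 to 253 ± 6.81 CPM (log2 1.80, SE 0.08, adjusted p = 8.9e-16) and Axin2 by a log2 of 1.06 (SE 0.07), while Lgr5 differed by 0.11 (SE 0.07, adjusted p = 0.20). In total 9307 genes passed, 4870 higher and 4437 lower, of which 2816 changed at least 2-fold.

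Only hypoxia and glycolysis genes passed both fry and camera with an estimated correlation in this comparison, with 17 of 19 lower and 1 higher (median -0.96, fry adjusted p = 2.6e-09, adjusted p = 0.013 with an estimated correlation). The oxygen sensor gene Egln3 fell by a log2 of -1.64 (SE 0.07). Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose by 2.07 (SE 0.09). Wnt/beta-catenin target genes rose in 11 of 18 with 1 lower (median 0.61, fry adjusted p = 1.1e-07, adjusted p = 0.15 with an estimated correlation), with the transcription factor Sox9 at 1.52. Notch pathway and secretory fate genes rose in 9 of 11, or 10 adjusted over the list alone (median 0.53, adjusted p = 0.092 with an estimated correlation), with the receptor genes Notch1 and Notch2 at 1.90 and 1.66. Cell cycle genes fell in 17 of 22 with 2 higher (median -0.36, adjusted p = 0.39 with an estimated correlation), with Cdk1 at -0.78 and Mki67 at 0.62. Cholesterol synthesis genes fell in 14 of 19, or 15 adjusted over the list alone, with 2 higher (median -0.56, adjusted p = 0.36 with an estimated correlation). Interferon-stimulated genes fell in 10 of 18 with 1 higher (median -0.75, adjusted p = 0.42 with an estimated correlation), and Paneth cell genes fell in 9 of 12 with 1 higher (median -0.59, adjusted p = 0.39 with an estimated correlation). All libraries of 1 treatment shared the RNA content and the Xist level described above, so treatment and library class cannot be told apart.

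The same comparison in Apc mutant organoids used libraries whose pathway targets went against their label (n = 3 and n = 2). In the libraries labelled mutant in conditioned medium, Wnt targets were lower and genes of differentiated cells far higher than in untreated mutant libraries. Notum was 420-fold lower (log2 -8.71, SE 0.14, adjusted p = 5.3e-25), Nkd1 fell by a log2 of -8.23 (SE 0.11) and Dkk2 was at least 57.6-fold lower. Sis rose from 9.95 ± 1.71 to 3735 ± 135 CPM, Muc2 from 2.71 ± 0.193 to 727 ± 112 CPM and Olfm4 by a log2 of 12.85 (SE 0.13). Apc rose by a log2 of 0.20 (SE 0.07, adjusted p = 0.012). In total 12278 genes passed, 6329 higher and 5949 lower, of which 6103 changed at least 2-fold. The largest increases were in RNAs without a poly(A) tail, such as Rpph1, the RNA of ribonuclease P, at 2264 ± 590 CPM and at least 23095-fold higher.

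Of 18 Wnt/beta-catenin target genes 14 were lower and 2 higher (median -1.32, adjusted p = 0.0064 with an estimated correlation), and of 6 secreted Wnt antagonists 5 were lower (median -5.22, or -4.75 at the bound). Enterocyte genes were higher in 21 of 22 with 0 lower (median 8.22, or 7.28 at the bound, adjusted p = 0.00088 with an estimated correlation), goblet cell genes in 11 of 11 (median 4.54, adjusted p = 0.0075 with an estimated correlation) and Paneth cell genes in 10 of 12 with 2 lower (median 6.56, adjusted p = 0.011 with an estimated correlation). ATF4 and amino acid response genes were lower in 17 of 17 (median -1.37, adjusted p = 0.014 with an estimated correlation), BMP target genes in 6 of 10 with 1 higher (median -2.09, adjusted p = 0.037 with an estimated correlation) and hypoxia and glycolysis genes in 16 of 19 with 2 higher (median -1.17, adjusted p = 0.019 with an estimated correlation). Bnip3, a mitophagy gene induced by low oxygen, fell by a log2 of -5.24 (SE 0.14). Fetal-like and regenerative epithelium genes were lower in 10 of 12 (median -2.98, adjusted p = 0.072 with an estimated correlation) and NF-kB and chemokine genes higher in 7 of 10 with 1 lower (median 2.13, or 1.90 at the bound, adjusted p = 0.15 with an estimated correlation). Between the effects of conditioned medium in both genotypes, 3309 genes were higher in both, with 1867 expected from independent calls, and 730 and 1044 went in opposite directions.

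The interaction of genotype and conditioned medium tested the difference between those effects on day 2, as the change in wild type minus the change in libraries labelled mutant. A positive value means a larger rise, or a smaller fall, in wild type. The same value equals the genotype difference without conditioned medium minus that within it. Medians of Wnt target and enterocyte genes thus lay near the 2.01 and -7.99 of the untreated comparison, while interferon-stimulated genes had 0.36 there. Treated and untreated libraries also differed in Y-linked expression, so a response of the same cells to the medium was not measured. It passed for 8764 genes, 4360 positive and 4404 negative. Axin2 gave 2.49 (SE 0.10), Lgr5 1.44 (SE 0.10) and Nkd1 9.43, while Sis gave -8.14, Lyz1 -9.41 and Chgb -7.03. Wnt/beta-catenin target genes were positive in 16 and negative in 1 of 18 (median 2.18, adjusted p = 0.0011 with an estimated correlation) and enterocyte genes negative in 20 and positive in 1 of 22 (median -8.00, adjusted p = 0.0011 with an estimated correlation). ATF4 and amino acid response genes were positive in 15 of 17 (median 1.21, adjusted p = 0.011 with an estimated correlation). Interferon-stimulated genes were negative in 11 and positive in 2 of 18, or 12 and 2 adjusted over the list alone (median -1.22, fry adjusted p = 2.1e-06, adjusted p = 0.24 with an estimated correlation). Stem cell genes had a median of 0.51, a mean of -0.84 and a test that pointed down (fry adjusted p = 0.00019), a call lost at adjusted p = 0.90 with an estimated correlation, where camera pointed up. Values of genes at 0 in a group depend on the prior count here.

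Day 4 was compared with day 2 within conditioned medium, first in the libraries labelled wild type (n = 3 and n = 3). Titles of all day 2 libraries in conditioned medium take another form than those of day 4. Change over culture time therefore cannot be told apart from a difference between separately made sets of libraries. Enterocyte, enteroendocrine cell, and NF-kB and chemokine genes rose, and hypoxia and glycolysis genes fell. Nfkbia, the inhibitor of NF-kB and itself a target of it, rose from 48.7 ± 1.92 to 121 ± 7.75 CPM (log2 1.31, SE 0.08, adjusted p = 2.6e-11), and Tnf from 1.80 ± 0.112 to 5.51 ± 1.07 CPM. Sis rose by a log2 of 0.62 (SE 0.06) and Muc2 from 343 ± 17.3 to 789 ± 118 CPM. Myc, a growth-promoting transcription factor, fell from 171 ± 2.27 to 84.3 ± 4.28 CPM (log2 -1.02, SE 0.07, adjusted p = 6.4e-11), and Clec2d, a lectin-like receptor gene, fell by -2.18 (SE 0.09). In total 3980 genes passed, 2059 higher and 1921 lower on day 4, of which 394 changed at least 2-fold.

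Of 22 enterocyte genes 17 rose, or 18 adjusted over the list alone, and 1 fell (median 0.30), and of 16 enteroendocrine cell genes 7 rose, or 9 (median 0.52). Both passed at fry adjusted p = 4.3e-05 and at adjusted p = 0.044 with an estimated correlation. NF-kB and chemokine genes rose in 7 of 10 (median 1.02) and hypoxia and glycolysis genes fell in 12 of 19, or 14 adjusted over the list alone, with 1 higher (median -0.27), both at adjusted p = 0.022 with an estimated correlation. Cell cycle genes fell in 15 of 22 (median -0.24), Paneth cell genes rose in 8 of 12 (median 0.45), Notch pathway and secretory fate genes fell in 6 of 11 with 1 higher (median -0.31), and ribosome biogenesis and nucleolar genes fell in 10 of 17, or 13 adjusted over the list alone (median -0.21). Those 4 lists were lost at adjusted p = 0.057 with an estimated correlation. Aurka, a mitotic kinase gene, fell by a log2 of -0.54 (SE 0.06), the Notch target gene Hes1 by -0.63 (SE 0.05) and Atoh1, the secretory fate factor, by -0.85 (SE 0.10). Interferon-stimulated genes did not pass (fry adjusted p = 0.86). Gm26917 took 10.6 ± 0.795% of gene counts on day 2 and 8.52 ± 0.327% on day 4, and mitochondrial genes 2.38 ± 0.145 and 3.04 ± 0.223%.

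In the libraries labelled Apc mutant, day 4 against day 2 was tested in the same way and with the same limit (n = 3 and n = 3). Stem cell and Wnt target genes fell. Olfm4 fell by a log2 of -0.52 and Axin2 by -0.56 (SE 0.06, adjusted p = 2.4e-07), while Lgr5 stood at 95.8 against 106 CPM (adjusted p = 0.090, and 0.043 with the replicate number as a block). Nos2 fell from 70.6 ± 3.60 to 19 ± 3.10 CPM (log2 -1.89, SE 0.11, adjusted p = 4.3e-11). Ace, a brush border peptidase gene, rose from 51.0 ± 7.42 to 163 ± 7.59 CPM (log2 1.68, SE 0.08). In total 3946 genes passed, 2007 higher and 1939 lower on day 4, of which 439 changed at least 2-fold.

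Of 14 crypt base stem cell genes 11 fell, or 12 adjusted over the list alone (median -0.46), and of 18 Wnt/beta-catenin target genes 10 fell (median -0.21), both with 0 higher and at adjusted p = 0.042 with an estimated correlation. Myc fell from 187 to 89.3 CPM. No other list held with an estimated correlation. Fibroblast and stromal and immune cell markers, with 3 members tested each and 1 higher in each, passed upward (fry adjusted p = 0.0052 and 0.0076). Both were lost at adjusted p = 0.40 with an estimated correlation. Pdgfrb rose from 1.03 to 2.68 CPM and Cd79b from 0.300 to 1.13 CPM. With the replicate number as a block, YAP target genes passed as lower (fry adjusted p = 0.0070), while tuft cell and oxidative stress (NRF2) genes no longer passed (0.079 and 0.050). Enterocyte genes rose in 13 of 22 with 1 lower (median 0.24, adjusted p = 0.18 with an estimated correlation), interferon-stimulated genes fell in 5 of 18 (median -0.33, adjusted p = 0.18 with an estimated correlation), Notch pathway and secretory fate genes fell in 7 of 11, or 8 adjusted over the list alone, where 1 was higher (median -0.36, adjusted p = 0.074 with an estimated correlation), and cell cycle genes fell in 10 of 22, or 11 (median -0.15, adjusted p = 0.27 with an estimated correlation). Isg15, a ubiquitin-like interferon target, fell by a log2 of -1.85 and Ly6a by -1.40. Between both labels, 1101 genes rose on day 4 in both, with 250 expected from independent calls, and 1070 fell in both, with 226 expected, while 34 and 19 went in opposite directions. Gm26917 took 10 ± 0.506% of gene counts on day 2 and 7.89 ± 0.189% on day 4.

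The interaction of genotype and day tested whether the change over time differed, as the change in libraries labelled wild type minus that in libraries labelled mutant. It passed for 351 genes, 205 positive and 146 negative, of which 38 reached a log2 difference of 1. Nos2 gave 2.34 (SE 0.18, adjusted p = 5.0e-08), having fallen in the labelled mutant libraries as given above and stood at 8.75 and 12.1 CPM on days 2 and 4 in labelled wild type. Duoxa2, the maturation factor of an epithelial oxidase, gave 2.25 (SE 0.37) and Tnf 1.71 (SE 0.22, adjusted p = 3.7e-05). Egln3 gave -1.04 (SE 0.09) and Ankrd37, another gene induced by low oxygen, -1.24. NF-kB and chemokine genes were positive in 5 of 10, or 6 adjusted over the list alone (median 0.92), and hypoxia and glycolysis genes negative in 7 of 19, or 13 adjusted over the list alone (median -0.37), both at adjusted p = 0.0017 with an estimated correlation. Stem cell genes were positive in 4 of 14, or 10 (median 0.28), and Paneth cell genes in 7 of 12, or 9 (median 0.46), both at adjusted p = 0.0045 with an estimated correlation, with Olfm4 at 0.61 (SE 0.07) and Lyz1 at 0.74 (SE 0.08). Wnt/beta-catenin target genes were positive in 2 of 18, or 9 adjusted over the list alone, and negative in 0 (median 0.25). They passed at fry adjusted p = 0.0027 and at adjusted p = 0.029 with an estimated correlation. Axin2 gave 0.26 (adjusted p = 0.13) and Lgr5 0.22 (adjusted p = 0.30), so neither passed as a single gene. The count of genes was 568 without the untreated libraries in the fit and 720 with the replicate number as a block.

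**Figure D3:**
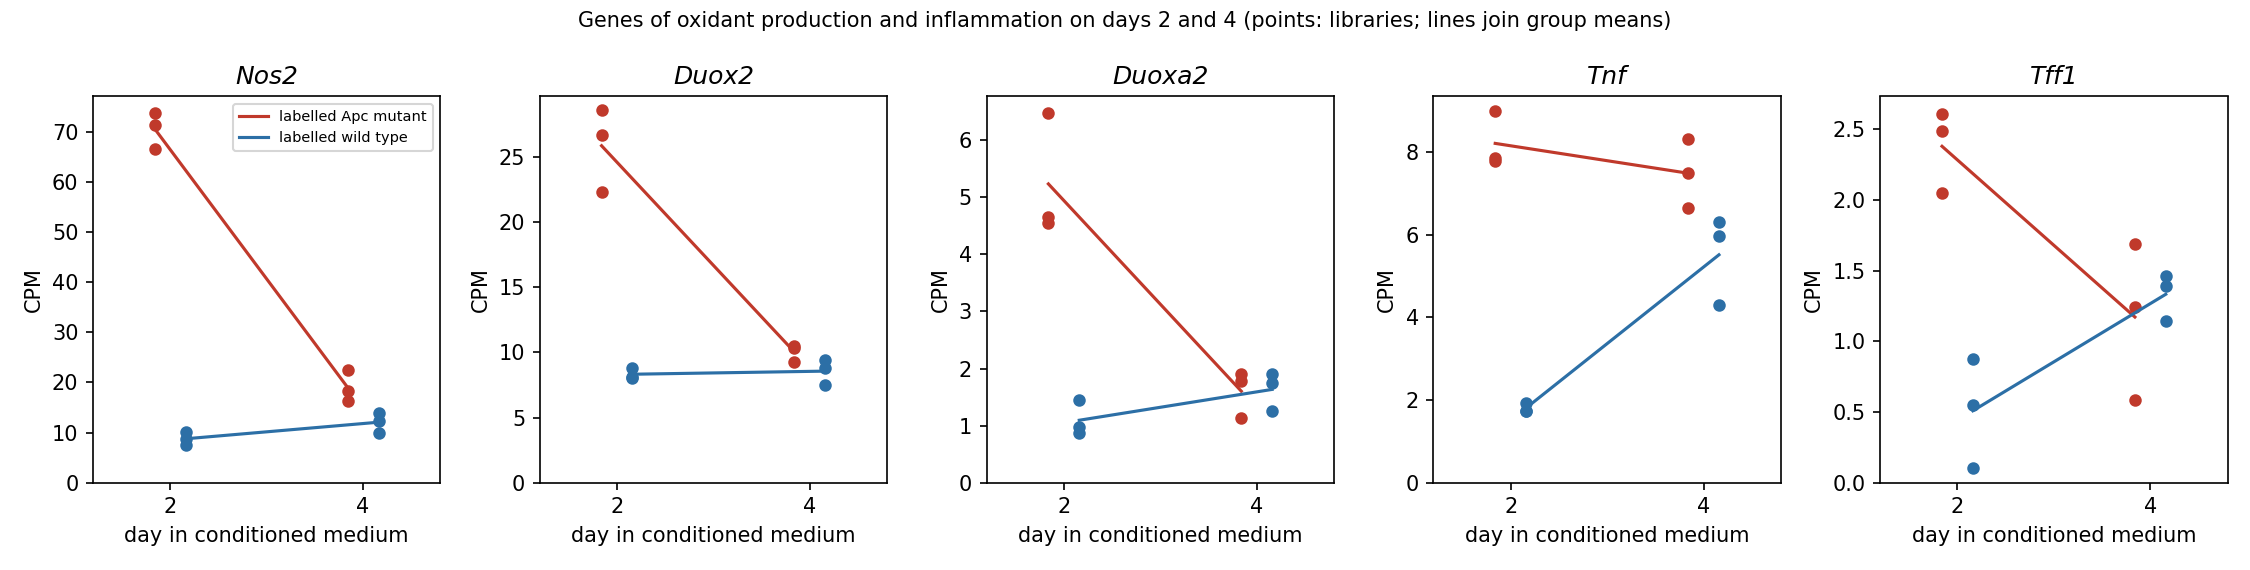
Levels in CPM (vertical axis) of Nos2, Duox2, Duoxa2, Tnf and Tff1 on days 2 and 4 (horizontal axis) in conditioned medium libraries labelled Apc mutant and wild type, as points for libraries and lines between group means. Nos2 stood at 70.6 and 19 CPM in the libraries labelled mutant and at 8.75 and 12.1 CPM in those labelled wild type on days 2 and 4, and Duox2 was chosen after its values were seen.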

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

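Tests of the first 2 patterns here, and the predictions for them, were chosen after the results were seen, while 3 of the 4 tests on chromosome 19 were written down beforehand. A difference between groups was marked where the interaction test passed. For genotype and conditioned medium on day 2 it passed for 8764 genes and 21 lists. This value contains the untreated genotype difference, so for genes nearly level between labels within conditioned medium it restates that comparison. The log2 difference was 1.605 for Apc, 2.49 for Axin2, 1.44 for Lgr5 and 9.125 for Notum. The largest positive differences were 13.62 for Ifitm1, 13.29 for Gbp8, 12.49 for Cdh13, 12.27 for Rasgrp3 and 12.19 for Kirrel, and the largest negative ones -14.68 for Cyp2c29, -14.32 for Sult6b2, -14.28 for Pycard, -14.22 for Enpep and -14.02 for Dmbt1. Most of these genes were at or near 0 in a group, so the fitted size depends on the prior count, and Ifitm1, Gbp8 and Cyp2c29 belong to families of similar sequence.

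For genotype and day in conditioned medium the interaction passed for 351 genes and 13 lists. The log2 difference was 2.34 for Nos2, 2.33 for Tff1, 2.25 for Duoxa2, 1.96 for Ifit1bl1 and 1.71 for Tnf, and -2.40 for Cyp2c37, -1.47 for Ppp1r3b, -1.43 for Cyp2c29, -1.31 for Ciart and -1.28 for Slc28a3. A signal in data outside the comparisons was the share of reads outside annotated features, at least 14.4% in conditioned medium libraries and at most 7.32% in untreated ones.

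The first pattern is that libraries labelled Apc mutant in conditioned medium lack the raised Wnt targets of the untreated mutant libraries. Library make-up that loses Wnt target transcripts is argued against for the 17 targets higher in the untreated mutant, as a set. Their median log2 fold change was 0.68 between conditioned medium and untreated wild type libraries. These libraries also differed in medium and in Y-linked expression, so library make-up was not tested alone. Notum, at 0.273 CPM in untreated wild type, was too low there to show a loss. The untreated mutant line itself, with its program lost in the medium, is argued against by 4 Y-linked genes, which summed to at least 381 CPM in the labelled mutant libraries in conditioned medium and at most 0.0611 CPM in the untreated mutant ones. Cells without the mutant program in both conditioned medium groups would leave the 772 genes at least 4-fold higher in the untreated mutant nearly level between labels, and their median log2 fold change was 0.18 on day 2 and -0.03 on day 4. That explanation was found from the same data, so it is a hypothesis that this value does not prove.

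The second pattern is that interferon-stimulated genes are higher and Wnt target genes lower in the libraries labelled Apc mutant within conditioned medium, where the Wnt call on day 2 (median -0.09) was lost at adjusted p = 0.25 with an estimated correlation. Unequal shares of counts taken by Gm26917 and Gm42418 are argued against for the interferon-stimulated genes, since the largest log2 shift that these shares allow between libraries of a day was 0.068 and the list medians were 1.36 and 0.88. Immune cells in the labelled mutant cultures stay open, since 9 of 12 immune markers were under the filter on low counts and their sum differed by -1.36 CPM on day 2, mostly from Itgam and Cd68, and by 0.379 CPM on day 4, where the B cell gene Cd79b was higher by a log2 of 1.14. The mutant genotype of the cells was left open for the interferon-stimulated genes by their median of 0.36 in the untreated mutant, and is argued against for the Wnt target genes, whose median there was 2.01.

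The third pattern is that genes of chromosome 19 are higher in the untreated mutant libraries, with a median log2 fold change of 0.53 over 553 genes against -0.09 to 0.09 on the 18 other autosomes. An extra copy of chromosome 19 would raise the whole chromosome, by 0.58 if every cell carried it, and the lowest median among 3 parts of it, ordered by position, was 0.43. For a few strongly changed genes, the share of the chromosome's genes above 0, 68.9%, fell between the bounds set beforehand and did not decide. With the most raised 10% of its genes left out, a test added afterwards, the median stayed at 0.40. A median moves little when 10% of genes are dropped, so this largely restates the 0.53. It argues only against a shift held by those genes alone. The expression level of the genes is argued against, since the highest median of 10000 matched random lists was 0.12. No biological explanation other than the copy number was tested.

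Libraries were also regrouped in other ways than by their labels. With 10 splits for each pair of groups in conditioned medium, splits are too few for a share under 0.05, and 1 split, the real one, reached the real count of genes and of lists in each case. The highest other count of genes was 0 for genotype on day 2, for genotype on day 4 and for day in wild type, and 1 for day in the libraries labelled mutant. Each other split mixed libraries of both groups, so a real difference between them widens the spread within groups and lowers these counts. They are therefore no measure of chance. For the interaction of genotype and day, 9 of 100 regroupings, the real one included, gave as many genes, with 1559 as the highest other. That count points to a structure of the samples, so the count of 351 did not stand apart. Regroupings with unequal numbers of day 4 libraries carry the change over days into the contrast, so they cannot decide the question. For lists, 1 of 100 gave as many, with 10 as the highest other. Among 44 regroupings with equal numbers of day 4 libraries in both genotypes, a comparison chosen afterwards, only the real one reached 351 and the highest other gave 1. In these others the change over days cancels from the contrast and widens the spread within groups. Low counts were thus set by the design, and no conclusion is drawn from them.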

How the results depend on the processing

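Alternatives were set beforehand except those named as added later, among them the fit without the untreated libraries. Of 16503 alternative values for 981 gene results, 15602 kept direction and side of the threshold, 743 lost the call, 158 gained it and 0 reversed, and of 3341 values for 225 list results 3050 kept both, 244 lost the call, 44 gained it and 3 reversed. With an absolute log2 fold change of at least 1 the counts of genes were 4779, 311 and 286 for genotype untreated, on day 2 and on day 4 in conditioned medium, 2816 and 6103 for conditioned medium in wild type and mutant, 394 and 439 for day in wild type and mutant, and 4054 and 38 for the interactions with medium and with day, because the threshold itself is stricter. Lists past camera with an estimated correlation numbered 7, 8, 6, 1, 9, 4, 2, 6 and 8 in the same order, and with the preset correlation 8 and 13 for conditioned medium in wild type and mutant. For the interaction of genotype and day, the count of genes was 568 with only the groups of the comparison. The fit without the untreated libraries holds the same libraries, so its count of 568 is the same result. The cause of the change in count was not tested. Leaving out 1 library at a time gave 1725 to 2484 genes for genotype on day 2, lowest without replicate 3 of the labelled mutant group, and 11 to 17 lists for genotype on day 4, lowest without replicate 3 of the labelled mutant group or replicate 1 or 3 of the labelled wild type group. The cause was not tested beyond the smaller number of libraries, and in untreated groups the lone library is assumed to vary like the others. Reversed was the fry direction of fibroblast and stromal cell markers in conditioned medium over untreated wild type with no filter on low counts, where the median was 0. Also reversed was the test of crypt base stem cell genes in the interaction of genotype and conditioned medium. Its median of 0.51 was matched by camera with an estimated correlation (adjusted p = 0.90). The preset correlation gave adjusted p = 0.85, and its direction was taken from the test with an estimated correlation. With the replicate number as a block, the interaction of genotype and day gave 720 genes, and no other count of genes moved by more than 1.5 times. Across all comparisons the block lost 16 and gained 4 calls among 169 list results and lost 17 and gained 21 among 742 gene results. For day in the libraries labelled mutant, where the numbers were read as pairs, it gained Lgr5, Dclk1, Tnfrsf10b, Polr1b and the YAP target genes, lost the tuft cell and the oxidative stress (NRF2) genes, and changed no other call. Where numbers were not read as pairs, it gave 1895, 1835 and 4921 genes and 13, 12 and 11 lists for genotype on day 2, genotype on day 4 and day in wild type, with correlations of same-numbered libraries of -0.18 to 0.10, -0.17 to 0.08 and -0.04 to 0.09 and 1, 1 and 0 of 3 libraries closest to their own number. In the untreated genotype comparison same-numbered libraries correlated at -0.64, and crossing the pairing gave 10537 genes, of which 10214 were among the 10319. Untreated libraries held at most 13027701 counts, which limits genes at 1 to 3 counts to the intervals given.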

Other observations

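Genes and tests here were chosen after the values were seen. Untreated Apc mutant organoids carried transcripts of the HoxA cluster, whose members set position along the body axis, that stood at 0 or 1 count in untreated wild type organoids. Hoxa9 stood at 43.5 ± 2.18 CPM (SD, n = 2) and Hoxa7 at 16.9 ± 0.253 CPM against 0, at least 310-fold and 121-fold higher, and Hoxa10 at 20.8 ± 0.645 CPM against 1 count, a ratio with a counting interval of 79.8 to 17660. Hoxa4 did not pass (adjusted p = 0.39 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Genes with regional expression went both ways. Onecut2, a transcription factor of the duodenum, fell from 262 ± 12.5 to 0.648 ± 0.0347 CPM, and Gata6, a factor of the small intestine, from 81.1 ± 5.24 to 19.3 ± 1.47 CPM. Gata4, a related factor, fell by a log2 of only -0.36 (SE 0.07), while Fgf15, a hormone of the ileum, rose from 0.327 to 31.4 ± 0.152 CPM, and Cdx2, a factor of the whole intestine, rose by 0.22 (SE 0.06). No list of such genes was tested.

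Within conditioned medium some single genes outside the lists differed by label on both days (n = 3 and n = 3), and no group of them was tested. Reg3g, an antibacterial lectin, stood at 459 ± 46.8 against 142 ± 4.29 CPM on day 2 and at 818 ± 44.4 against 284 ± 13.9 CPM on day 4. Reg4, a lectin of secretory cells, was higher by a log2 of 1.32 and 1.23. Isx stood at 109 ± 5.69 against 31.5 ± 3.45 CPM on day 2, and its targets Bco1 and Scarb1, an importer of carotenoids, were lower by -1.70 and -0.41 on day 2 and by -2.50 and -0.66 on day 4. Duox2, an epithelial oxidase, stood at 25.9 ± 3.23 against 8.33 ± 0.404 CPM on day 2, did not pass on day 4 (adjusted p = 0.16) and gave an interaction of 1.39 (SE 0.15, adjusted p = 4.7e-06).

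A hypothesis for the missing Wnt program is that both conditioned medium groups hold cells without the mutant program, for example wild type organoids given medium of different sources. The protocol names medium from mutant and from wild type cultures. The library titles hold APCCM or WTCM, which can be read as the source of the medium and would go with that example. The treatment label names mutant medium for all 12 treated libraries, which goes against that example. The hypothesis was found from the values given above, medians of 0.18 on day 2 and -0.03 on day 4 for cells without the mutant program in both conditioned medium groups. They are therefore no independent test of it, none was run, and no group was reassigned.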
